A study of Rattus norvegicus with 12 samples.

How the data were processed

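The series holds 12 Illumina rat BeadChip arrays of total RNA from dissociated dorsal root ganglion (DRG) neurons of Sprague Dawley embryos at embryonic day 16.5, in 3 groups of 4 arrays. One group was left as wild type, one overexpressed EGFP, and one overexpressed the ICD, the intracellular domain of type III neuregulin 1. The sample titles, the design text and the column headers call the control EGFP, whereas the source and genotype labels of the same 4 samples say ECD. The name EGFP is used throughout, and the conflict between the labels is not settled. Column headers of the scanner table mark the wild-type arrays as not infected and the ICD arrays as the C-terminal tail, and each column was matched to its group through these words only. According to the design text, each condition had 4 biological and 2 technical replicates. Whether the technical replicates were averaged before the values were exported is not given in the sources used here, so the p-values measure only the spread between these 12 arrays.

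RNA was labelled with biotin after linear amplification and detected with streptavidin-Cy3, per the labels' protocols. GenomeStudio is the only program that the submitters' processing notes name, with no version. The non-normalised table holds the deposited probe intensity on a linear scale with a detection p-value beside each intensity, per the file headers. A second deposited table holds the authors' processed values. Its 12 columns share one distribution with a median of 6.94, so its values are on a log2 scale after quantile normalisation, as read from the deposited values, and no centring of genes was seen. For all 12 scanner columns the closest processed column belonged to the same group, with r of at least 0.996. The processed table served as an alternative.

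The analysis started from the 22523 probe intensities. Background was corrected and arrays were quantile normalised with neqc of limma 3.58.1 in R 4.3.3. Negative controls were inferred from the detection p-values and the offset was 16. Probes with a detection p below 0.05 on at least 4 of the 12 arrays were kept, which left 11580 probes. Gene names came from the platform annotation, in which 13793 probes had 1 symbol, 0 had several and 8730 were unnamed here. Through the gene identifier 13752 symbols were updated to the reference gene table, 5 through the accession, and 36 kept the name of the array annotation. The brightest probe stood for a gene, which gave 8120 genes. Genomic positions are not given, because the sources used here name no genome build for the probes.

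Each of the 3 comparisons was fitted with limma (lmFit and eBayes, two-sided) over all 12 arrays with 1 mean per group. The p-values were adjusted by Benjamini-Hochberg over the 11580 probes, with a threshold of 0.05. A dim gene that was detected on no array of a group is given as at least a number of folds, against the higher of the weakest detected signal and its own signal on each array. Gene lists, 24 in number with 431 symbols, were fixed before the data were examined, as were the comparisons, the thresholds and the rule for the genes that are named. Lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. The endothelial list with 3 measured genes and the macrophage list with 2 were too small. Named are the 8 genes with the largest change each way among those past the threshold whose groups do not overlap, or the 5 with the smallest p each way where fewer than 5 passed. One gene that this rule picks is not reported here. Nrg1, Ptgds and up to 4 list members with the smallest p were added. Nrg1 and Ptgds, the latter because the study is known for it, were also tested with an exact permutation test over the 70 assignments of 4 against 4 arrays, which cannot give a p below 0.0286.

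The column headers carry the rat numbers 2, 3, 6 and 7 in each group, and the same number was read as the same rat. Of the 12 pairs of arrays that share a rat number, 10 deviated from their group means with a correlation over 0.1. Their median correlation was 0.49, against -0.25 for arrays of different rats, and the 2 weaker pairs, the lowest at -0.06, both contain the ICD array of rat 7. The fit has no block, as fixed beforehand. The block planned then was the replicate number of the titles, and on the scanner values the rat number of the headers stands in for it, since the columns carry no title number. The value with the rat as a block is given beside a result where it changes the call or a count by more than 1.5 times. The arrays also fall into 2 sets by background. The 6 arrays of rats 2 and 3 had median intensities of 92.7 to 109.5 and the 6 of rats 6 and 7 had 128.4 to 156.1. Each set holds all 3 groups, so values within each set are given as well. The median of -0.25 pools pairs within and across these sets. Correlations of different rats ran from -0.22 to 0.42 within a set and from -0.62 to 0.35 across sets. The gap from 0.49 therefore partly reflects the sets. By mean correlation, 9 of the 12 arrays were closest to their own rat number. That equal numbers mean the same rat remains a reading of the headers.

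Recovery was tested on simulated data with the real probe means and spreads. Over 11580 probes, 71% of the probes changed by 1 on the log2 scale were called in the ICD and EGFP comparison, 71% between ICD and wild type and 82% between EGFP and wild type. For changes of 2 these shares were 96%, 93% and 98%. The simulated values were drawn independently for each probe and array, whereas real arrays of one rat and real genes vary together. These shares are therefore no measure of the power in the real data. The alternatives were no background correction, normexp without negative controls (offset 50), median scaling, cyclic loess, the authors' values, other detection filters, trended and robust moderation, array weights, only the compared groups, the rat block, stricter thresholds, the probe of the smallest p, a plain two-sample test, and each array left out in turn. Blocks by background set, either set alone, the rat block with each array left out, the authors' values with the number in the sample titles as a block, and the rat block beside the fibroblast list as a covariate for Ptgds were added after the data had been seen. A slide block was not run, since the sources used here give no slide. The number of arrays limits the precision.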

Results

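Expression was measured on 12 arrays of embryonic rat DRG neurons, with 4 arrays each for uninfected wild-type neurons, for neurons overexpressing EGFP and for neurons overexpressing the ICD. The ICD is the cytoplasmic tail of type III neuregulin 1, a transmembrane ligand on axons that signals to ErbB receptors on Schwann cells. Between 10596 and 11445 of the 22523 probes were detected per array. Arrays of one group correlated at r of 0.974 to 0.992 over the kept probes. The design sets the ICD neurons against both controls and so asks which genes change when the ICD is overexpressed. The wild-type neurons were not infected, so the EGFP control differs from them in infection as well as in the overexpressed protein.

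Nrg1 was read from 1 kept probe. Its mean log2 intensity was 8.11 ± 1.18 (SD, n = 4) in ICD neurons, 8.59 ± 1.21 in EGFP neurons and 8.56 ± 0.82 in wild-type neurons. The differences of -0.48 from EGFP and -0.46 from wild type did not pass (exact permutation p = 0.543 for both, two-sided). Within rats ICD lay below wild type in 4 of 4, by -1.05 to -0.06 (exact paired permutation p = 0.125, the smallest that 4 pairs allow), and below EGFP in 3 of 4. The probe's place on the transcript is not given in the sources used here, so it does not show whether the introduced ICD was expressed. Rat 6 had the highest Nrg1 signal in every group, at 9.77 in wild type, 10.37 in EGFP and 9.70 in ICD neurons.

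Ptgds, which encodes the lipocalin-type prostaglandin D2 synthase, had the largest difference in the comparison of ICD with wild-type neurons. Its mean log2 intensity was 10.05 ± 1.74 in ICD, 6.97 ± 1.37 in EGFP and 5.50 ± 1.06 in wild-type neurons (SD, n = 4). It was detected on 4 of 4 ICD arrays, 3 of 4 EGFP arrays and 1 of 4 wild-type arrays, so folds against wild type rest on a signal near background. ICD exceeded wild type by 4.55 ± 0.85 (SE), a 23.5-fold difference with a 95% interval of 6.53 to 84.5 (limma adjusted p = 0.047), with an exact permutation p of 0.0286, the smallest that 70 assignments allow, or 0.171 after adjustment over 6 such tests. Within rats it was above 0 in 4 of 4 (exact paired permutation p = 0.125, the smallest possible). ICD exceeded EGFP by 3.08 ± 0.85, or 8.46-fold, in 3 of 4 rats, with differences from -0.43 in rat 6 to 5.46 in rat 3. On the EGFP array of rat 3 Ptgds was not detected, at 5.09, so the 5.46 rests on a signal near background. The mean difference of 3.08 did not pass over all genes (limma adjusted p = 0.9998, and 0.933 with the rat block), nor in the exact permutation test (p = 0.0571, or 0.171 after that adjustment, and exact paired permutation p = 0.25). EGFP exceeded wild type by 1.47 ± 0.85 in 3 of 4 rats (exact permutation p = 0.143). The Ptgds difference between ICD and wild type was 3.10 without background correction (limma adjusted p = 0.0688) and 3.26 with the authors' values (limma adjusted p = 0.0574), and it did not pass without a filter on dim probes (limma adjusted p = 0.104) or in 9 of the 12 fits with 1 array left out. Without the ICD array of rat 7 the difference from EGFP was 2.41 and that from wild type 3.87, the latter with a limma adjusted p of 0.169.

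**Figure D1:**
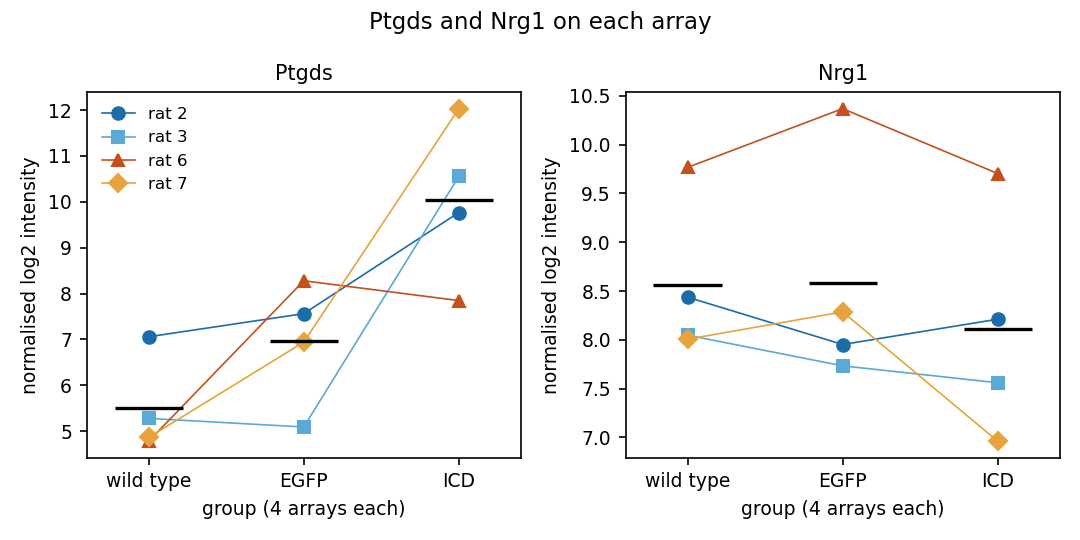
Normalised log2 intensity (y axis) of Ptgds on the left and Nrg1 on the right in the 3 groups (x axis), where points are single arrays, lines join the arrays of one rat and black bars are group means. Ptgds averaged 10.05 in ICD neurons against 6.97 in EGFP and 5.50 in wild-type neurons, with rat 6 the only rat in which ICD was not above EGFP, and Nrg1 was highest in rat 6 in every group.

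No gene separated ICD from EGFP neurons over all genes tested. limma called 0 of 8120 genes higher or lower, with a smallest adjusted p of 0.9998. At an unadjusted p under 0.05, 123 genes were higher and 52 lower, 175 in all, fewer than the 5% that chance alone gives. With the rat as a block limma also called 0 genes, with a smallest adjusted p of 0.933. The block had 357 genes at the unadjusted level and a plain two-sample test 116, each also under that share. Among the genes with the smallest p, Ctsh (cathepsin H) differed by 0.90 ± 0.22 and Pm20d1 by 0.51 ± 0.14 (log2 ± SE, ICD minus EGFP), each higher in ICD in 4 of 4 rats. Gsdmd, which encodes the pore-forming gasdermin D, was detected on 4 of 4 ICD and 0 of 4 EGFP arrays and was at least 1.18-fold higher in ICD. On the other side stood Ndst3 (a heparan sulfate sulfotransferase) at -0.62 ± 0.13, Spata24 at -0.68 ± 0.19, Nhlrc2 at -0.46 ± 0.14 and Erich2 at -0.46 ± 0.14, all lower in ICD in 4 of 4 rats. The vomeronasal receptor gene Vom2r32 was detected on 0 of 4 ICD and 4 of 4 EGFP arrays and was at least 1.27-fold higher in EGFP. The adjusted p of each of these genes was 0.9998. All were dim, at 4.89 to 6.73 on ICD and EGFP arrays, against 4.78 to 5.28 for Ptgds on arrays where it was not detected. In ICD neurons Nhlrc2 and Pm20d1 overlapped wild type. In 4 of 4 rats EGFP lay above wild type for Nhlrc2 and below it for Pm20d1, so these differences rest largely on EGFP. Every ICD array lay outside the wild-type range for Ctsh, Gsdmd and Ndst3, but not for Spata24, Erich2 and Vom2r32.

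By camera with the preset correlation, the fibroblast and mesenchymal markers, the extracellular matrix genes and the immediate early genes lay higher as groups in ICD than in EGFP neurons. None of the 3 passed with an estimated correlation (adjusted p = 0.359 for each) or by fry (adjusted p = 0.492 for each), nor did any other of the 22 tested lists. All 13 measured fibroblast markers lay above 0, with a mean of 0.56 (camera adjusted p = 1.1e-06), for example Col1a2 at 0.86 ± 0.41 and Col3a1 at 0.73 ± 0.38. The 5 Schwann cell and satellite glia markers of low wild-type level averaged 0.47, and the fibroblast mean exceeded theirs in only 2 of 4 rats, by 0.08 on average (95% interval -0.51 to 0.68). Of the 12 matrix genes 10 lay above 0, with a mean of 0.51 (camera adjusted p = 4.7e-05), led by the collagen cross-linking enzyme Lox at 1.01 ± 0.42. The 11 immediate early genes averaged 0.36 (camera adjusted p = 0.0007), with Ier2 at 0.69 ± 0.36, and their mean was 0.23 without the ICD array of rat 7, or 0.13 with the rat block as well, where the call was lost (adjusted p = 0.0748). No single member passed over all genes, and 0 members of these 3 lists passed when adjusted over the list alone. With the rat block 6 lists passed camera. The added ones were cholesterol biosynthesis with a mean of -0.19 (0 of 11 members above 0, adjusted p = 0.005), nerve injury and regeneration with 0.15 (adjusted p = 0.016) and p53 targets with 0.24 (adjusted p = 0.025). With the block and an estimated correlation these 3 had adjusted p of 0.497, 0.497 and 0.434, and fry did not pass them. The first 2 rested largely on rat 7, since the cholesterol differences were -0.10, -0.10, 0.14 and -0.71 and the nerve injury differences -0.22, 0.02, 0.24 and 0.56 in rats 2, 3, 6 and 7. The shift depended on the rats, since the fibroblast mean was 0.02 in rats 2 and 3 and 1.09 in rats 6 and 7, the matrix mean 0.02 and 1.003, and the immediate early mean 0.04 and 0.66. Without rat 7 the differences within rats averaged 0.25 for the fibroblast list and 0.22 for the matrix list. These 2 lists kept their camera call in all 12 fits with 1 array left out. Ptgds passed within the prostaglandin list (limma adjusted p over the list alone = 0.0295), though not over all genes. Since the study is known for Ptgds, a pass within a short list that holds it is no independent support. The mean of that list, 0.39, did not pass camera. Among the neuron-to-Schwann-cell signals 0 members passed over the list alone, or 1 with the rat block.

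Genes that separated ICD from wild-type neurons included Col3a1, Sparc and Myl9 among the higher and Hoxd1 and Htr2a among the lower ones. limma called 51 of 8120 genes, 47 higher and 4 lower, with adjusted p between 0.0409 and 0.0474, and 804 genes had an unadjusted p under 0.05 (1285 with the rat block). Besides Ptgds, the largest rises were Col3a1 (collagen III) by 2.07 ± 0.38, the myosin light chain gene Myl9 by 2.05 ± 0.37, Gask1b by 2.01 ± 0.38 and Sparc, a collagen-binding matrix protein, by 1.95 ± 0.37 (log2 ± SE). They were followed by the protease gene Prss23 at 1.92 ± 0.35, the actin-binding Cald1 at 1.89 ± 0.36 and the carboxypeptidase gene Cpz at 1.88 ± 0.37. Each was higher in ICD in 4 of 4 rats and had an adjusted p of 0.047. The 4 genes that fell were Hoxd1, a homeobox gene of embryonic sensory neurons, by -1.19 ± 0.21, the chondroitin sulfotransferase gene Chst15 by -1.004 ± 0.184, Pgc by -0.88 ± 0.17 and the serotonin receptor gene Htr2a by -0.80 ± 0.12. With the rat as a block the count was 198 (180 higher, 18 lower) and held all 51, but with the block it was 0 without the wild-type array of rat 7 or the ICD array of rat 6, 1 without wild-type rat 3, 2 without ICD rat 3 and 13 without wild-type rat 2. It was 153 with the block and without the ICD array of rat 7, which did not vary with the other arrays of its rat number. With the background set as a block it was 91 (80 higher, 11 lower), and within rats 2 and 3 or within rats 6 and 7 alone it was 0 each. The count depended on single arrays. It was 0 without the wild-type array of rat 3, 6 or 7, the EGFP array of rat 3 or 6, or the ICD array of rat 2, 6 or 7, and it was 93 without wild-type rat 2, 119 without EGFP rat 2 and 88 without ICD rat 3.

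By camera with the preset correlation, 7 of the tested lists lay higher in ICD than in wild-type neurons. With an estimated correlation no list passed (smallest adjusted p = 0.0949). The 13 fibroblast and mesenchymal markers had a mean of 1.502 (camera adjusted p = 3.7e-17), from Pdgfra at 0.25 to Col3a1 at 2.07. Among them Postn (periostin) at 1.70 ± 0.23, Col3a1 and Sparc passed over all genes, 11 passed when adjusted over the list alone, and 8 passed over all genes with the rat block, including Col5a1 at 1.80 ± 0.38 (adjusted p = 0.0643 without and 0.0356 with the block). The 12 matrix genes had a mean of 1.07 (4.7e-09). Lox at 2.005 ± 0.42, the protease gene Mmp14 at 1.80 ± 0.37 and Thbs2, detected on 0 of 4 wild-type arrays and at least 2.48-fold higher in ICD, were among the 8 that passed over the list alone, and all 3 passed over all genes with the block (adjusted p = 0.0601, 0.0586 and 0.0541 without and 0.0393, 0.0241 and 0.0477 with it). The 19 nerve injury and regeneration genes all lay above 0, with a mean of 0.62 (2.4e-06). Only Anxa1 at 1.47 ± 0.30 and the small heat shock protein gene Hspb1 at 1.38 ± 0.32 passed over the list alone, or 6 genes with the block, where both also passed over all genes (adjusted p = 0.0237 and 0.0384). The injury-induced transcription factor gene Atf3 was at 0.84 ± 0.72. The 10 p53 targets averaged 0.61 (0.00011), with Gdf15 at 1.12 ± 0.26, the cell cycle inhibitor gene Cdkn1a at 1.41 ± 0.38 and the death receptor gene Fas, detected on 0 of 4 wild-type arrays and at least 1.15-fold higher, among the 5 that passed over the list alone. All 3 passed over all genes with the rat block (adjusted p = 0.0335, 0.0406 and 0.0384). Over the p53 list alone, 6 genes were higher and 1 lower with the block, against 5 and 0 without it. The 11 immediate early genes averaged 0.65 (4.3e-05), with Klf4 at 1.42 ± 0.34, Ier3 at 1.20 ± 0.33 (adjusted p = 0.145 without and 0.042 with the block) and Fos, detected on 0 of 4 wild-type arrays, at least 1.11-fold higher. There 4 genes passed over the list alone, or 7 with the block. The 15 interferon-stimulated genes averaged 0.37 (0.0015), with Gbp2 at 1.66 ± 0.28 past the threshold over all genes (3 members with the block) and Irf7 at 0.86 ± 0.19 over the list alone (adjusted p over all genes = 0.0747 without and 0.0483 with the block). The 9 neuron-to-Schwann-cell signals averaged 0.34 (0.039, a call lost in 4 of 12 fits with 1 array left out, and a mean of 0.0131 under strict detection), with Ncam1 at 0.76 ± 0.20 (over all genes with the block, adjusted p = 0.0347) and the Notch ligand gene Jag1, detected on 0 of 4 wild-type arrays and at least 1.68-fold higher, past the threshold over the list alone. By fry 7 lists passed, with the heat shock list in place of nerve injury (fry adjusted p = 0.187 without and 0.042 with the block). With the block fry passed 9 lists, among them prostaglandin synthesis and receptors (fry adjusted p = 0.140 without and 0.0245 with it, with 1 and 2 members past the threshold over all genes, and over the list alone 2 higher without it and 3 higher and 1 lower with it) and pan-neuronal markers (0.457 and 0.0382), and no longer heat shock (0.0366 and 0.061). The pan-neuronal list lay lower in ICD, with a mean of -0.06 and 5 of 18 members above 0.

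**Figure D2:**
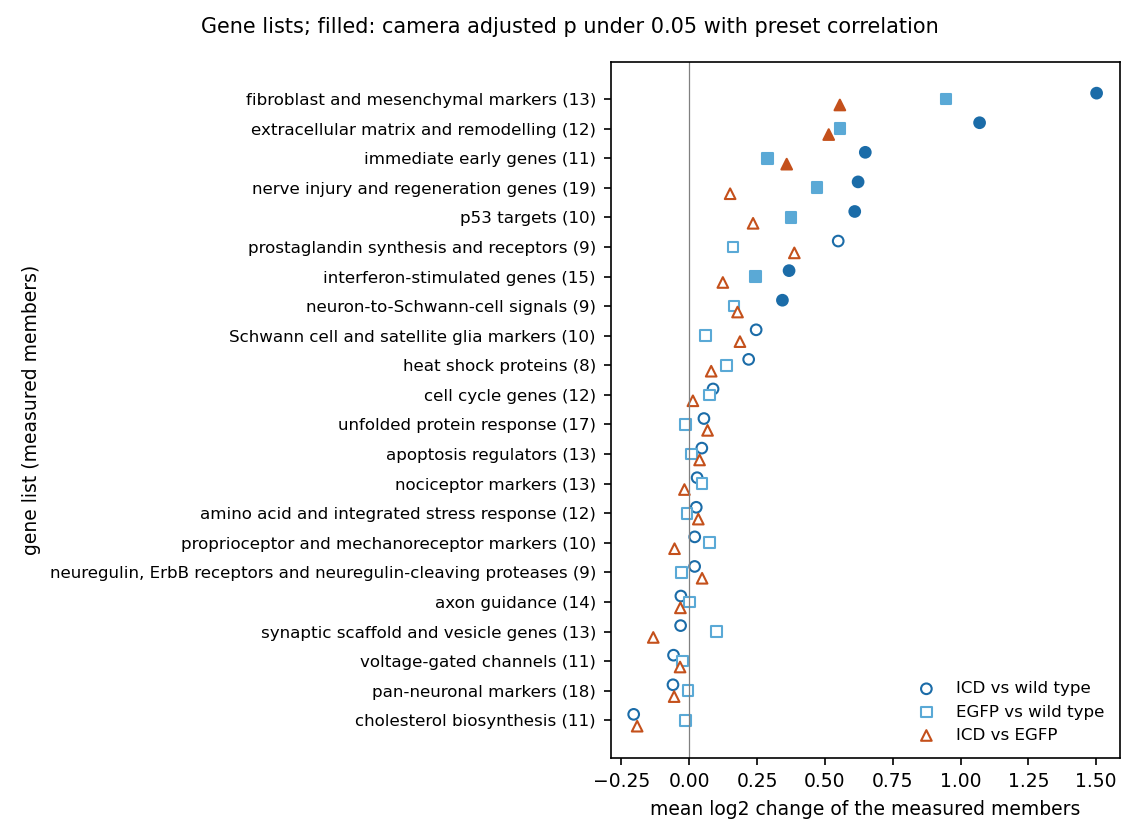
Mean log2 change of the measured members (x axis) of the 22 tested lists (y axis, members in parentheses) for ICD against wild type (circles), EGFP against wild type (squares) and ICD against EGFP (triangles), filled where camera with the preset correlation passed. The fibroblast list lies at 1.502, 0.95 and 0.56 in these 3 comparisons and the pan-neuronal list at -0.06, -0.004 and -0.06.

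Between EGFP and wild-type neurons no single gene passed. limma called 0 of 8120 genes (smallest adjusted p = 0.385, and 0.138 with the rat block). At an unadjusted p under 0.05, 228 were higher and 188 lower, 416 in all, close to the 5% that chance alone gives. The plain two-sample test had 420 genes and the rat block 730 at that level. With the rat block and without the ICD array of rat 7, 73 genes passed (66 higher, 7 lower). The genes with the smallest p included Postn at 1.32 ± 0.23, the proteoglycan gene Vcan at 1.54 ± 0.33, the interferon-induced Ifitm3 at 1.31 ± 0.27 and the anion channel gene Lrrc8a at 1.11 ± 0.21 (log2 ± SE, EGFP minus wild type), each higher in EGFP in 4 of 4 rats. The mesenchymal transcription factor gene Prrx1 was detected on 4 of 4 EGFP and 0 of 4 wild-type arrays, at least 1.46-fold higher. Lower in EGFP in 4 of 4 rats were Htr2a at -0.69 ± 0.12, Hoxd1 at -0.86 ± 0.21, Chst15 at -0.77 ± 0.18 and the phosphatase gene Dusp7 at -0.52 ± 0.13. Adam6 was detected on 0 of 4 EGFP and 4 of 4 wild-type arrays and was at least 1.19-fold higher in wild type. By camera 6 lists lay higher in EGFP, and none of them passed with an estimated correlation (smallest adjusted p = 0.256) or by fry (0.293). They were fibroblast markers with a mean of 0.95 (adjusted p = 3.9e-13), matrix genes with 0.56 (1.9e-05), nerve injury with 0.47 (3.9e-05), p53 targets with 0.37 (0.0023), interferon-stimulated genes with 0.24 (0.012) and immediate early genes with 0.29 (0.035, a call lost in 4 of 12 fits with 1 array left out, where the mean ranged from 0.13 to 0.42). Without the EGFP array of rat 2 the nerve injury mean was 0.16 (adjusted p = 0.259) and that of p53 targets 0.24 (adjusted p = 0.0919), and the interferon call was lost in 2 of the 12 fits (adjusted p up to 0.0899). Of the fibroblast markers 7 passed when adjusted over the list alone. The nerve injury mean was 0.83 in rats 2 and 3 and 0.12 in rats 6 and 7, whereas the fibroblast mean was 1.12 and 0.77. The matrix mean ranged from 0.35 to 0.70 over the 12 fits with 1 array left out, with no camera call lost. Over 41 alternatives it ranged from 0.26 to 0.85, and 2 of them lost the call.

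No gene passed in both ICD comparisons (limma, 0 with or without the rat block). In both, 105 genes had an unadjusted p under 0.05, 86 higher and 19 lower in ICD, against 37 by a plain two-sample test. With the rat block they were 229, 173 higher and 56 lower. The ICD arrays are shared by the 2 ICD comparisons, so their noise alone can put genes in both. A value for unchanged groups is not given for this overlap, so it is no evidence of an ICD effect. The 51 genes called between ICD and wild type all had the same sign between EGFP and wild type, and 47 of them had an unadjusted p under 0.05 there. Since both comparisons against wild type use the same wild-type arrays, simulated unchanged groups gave the same sign for 87.7% of the top genes. For the 47 higher genes the median change was 1.56 in ICD and 1.02 in EGFP, each against wild type, and 0.61 between ICD and EGFP, where none passed. Across genes, which are not independent replicates, the changes of ICD and of EGFP from wild type correlated at r = 0.82, against 0.50 in simulated data with no effect. Their covariance was 0.0667 against a simulated 0.0264. When ICD was set against 2 of the wild-type arrays and EGFP against the other 2, the correlation lay between 0.06 and 0.63 over the 6 such splits. These splits set different rats against each group, so the range also holds differences between rats. The mean covariance over the splits was 0.0427, against 0.0403 for the observed minus the simulated covariance.

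**Figure D3:**
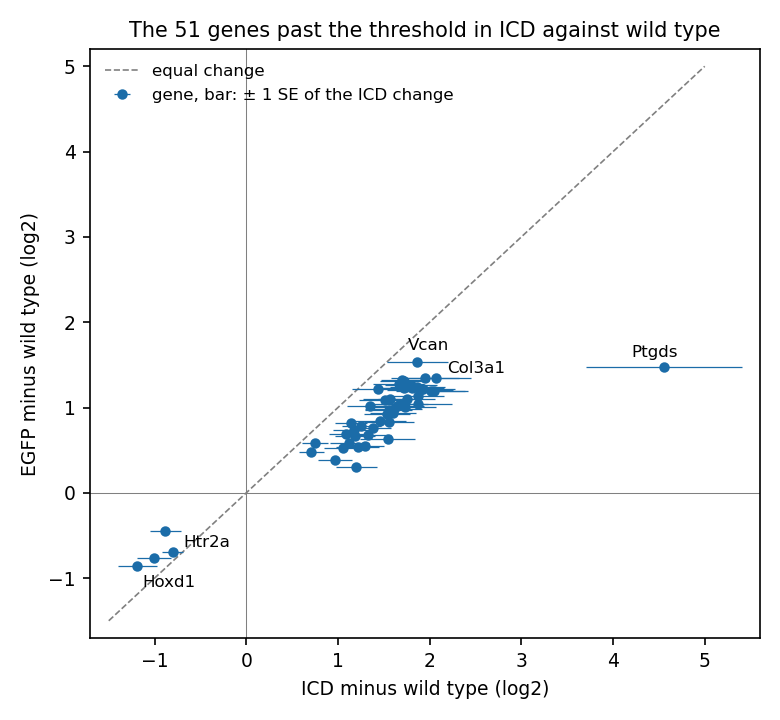
Log2 change of EGFP from wild type (y axis) against that of ICD from wild type (x axis) for the 51 genes past the threshold in the latter, with bars of 1 SE for the ICD change and a dashed line of equal change. All 51 points share their sign on both axes, with Ptgds at 4.55 in ICD and 1.47 in EGFP.

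Among the tested marker lists of cell types, only the fibroblast list passed camera in any comparison, and it did not pass with an estimated correlation (smallest adjusted p = 0.0949). The 18 pan-neuronal markers averaged -0.06 between ICD and wild type, -0.06 between ICD and EGFP and -0.004 between EGFP and wild type. Between ICD and wild type this list was lower by fry with the rat block (fry adjusted p = 0.0382, and 0.457 without it), though not by camera. Nociceptor markers averaged 0.03 and proprioceptor and mechanoreceptor markers 0.02 between ICD and wild type, although in the latter list Spp1 at 1.77 ± 0.43 and the transcription factor gene Maf at 0.67 ± 0.19 passed when adjusted over the list alone. With the rat block 3 members of that list were higher and 2 lower over the list alone. The 10 Schwann cell and satellite glia markers averaged 0.25, with none past the threshold and Apoe at 1.72 ± 0.62 (adjusted p = 0.333, and 0.0337 with the rat block). In the list of neuregulin, its receptors and its proteases, with a mean of 0.02, Adam17, a protease that sheds neuregulins, was the only member to pass, at 0.71 ± 0.14 (adjusted p = 0.047). Adam17 was also higher in EGFP than in wild type, by 0.48, and passed there when adjusted over the list alone. The 15 lists that did not pass between ICD and wild type had means from -0.20 to 0.55 (smallest camera adjusted p = 0.199). Fibroblast markers moved with the groups on single arrays too. Their mean log2 intensity was 8.76 to 9.98 on wild-type arrays, 9.70 to 10.89 on EGFP arrays and 10.36 to 11.23 on ICD arrays, the highest being the ICD array of rat 7.

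**Figure D4:**
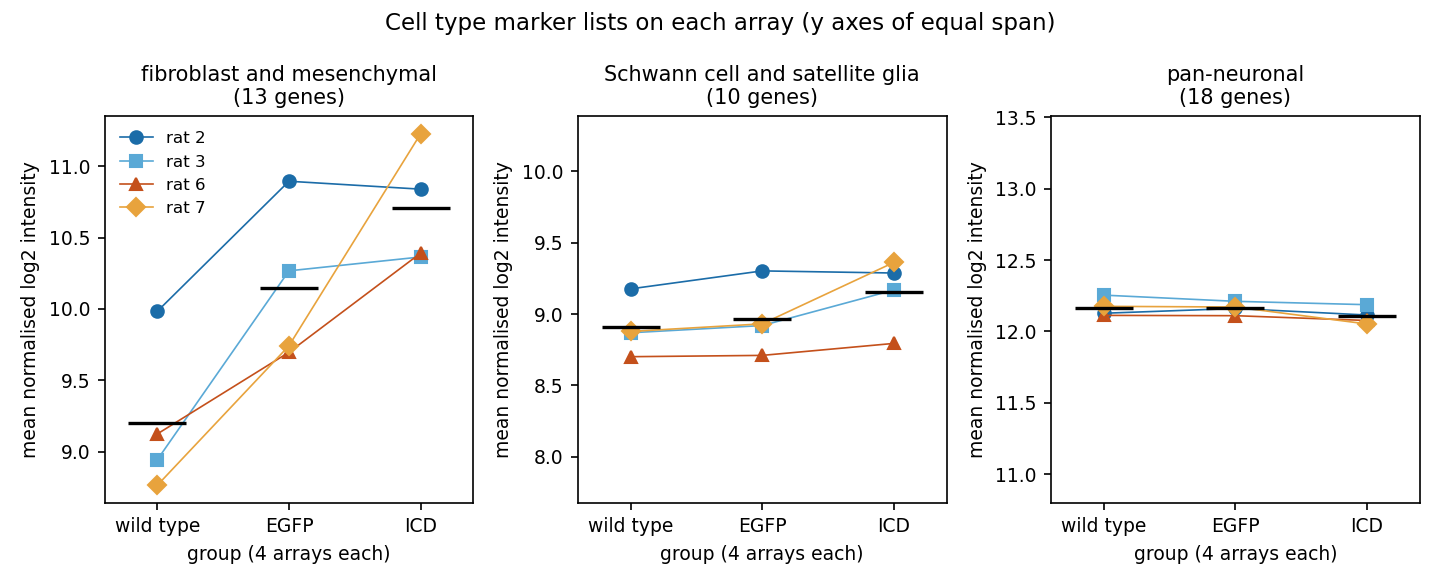
Mean normalised log2 intensity (y axis, equal span in each panel) of fibroblast, glia and pan-neuronal markers in the 3 groups (x axis), where points are arrays, lines join the arrays of one rat and black bars are group means. Fibroblast markers lay above the wild-type array of the same rat on every EGFP and ICD array, while the pan-neuronal mean differed between groups by at most 0.06.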

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

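Single values far from the other 3 arrays of their group were looked for in 243 groups of 4 arrays, over 57 named genes, 22 lists and 2 array measures, and 10 were found, against the 5% that chance gives. Klf4 was at 8.60 on the ICD array of rat 7, where the others lay between 7.06 and 7.23. Ier3 was at 8.71 and Ifitm3 at 9.10 on the wild-type array of rat 2, with the others at no more than 7.77 and 8.09. Gsdmd was at 4.96 on the wild-type array of rat 3, below 5.21 on the next. Lrrc8a was at 6.17 on the ICD array of rat 2, below 6.84. Slc7a5, an amino acid transporter gene, was at 10.07 on the EGFP array of rat 3, below 10.64, and at 10.68 on the ICD array of rat 3, above 10.28. The mean of the unfolded protein response list was 9.84 on the wild-type array of rat 7, below 9.98. The cholesterol biosynthesis list was at 12.01 on the ICD array of rat 6, where the others were between 11.02 and 11.15. On the wild-type and EGFP arrays of rats 6 and 7 that list lay at 11.73 to 11.87, so the ICD array of rat 6 was close to its set. The value of 11.02 was that of the ICD array of rat 7. The synaptic list was at 8.27 on the wild-type array of rat 6, above 8.19. All tests of the explanations weighed here were chosen after the results had been seen, except the counts over other splits of the arrays.

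Fibroblast and mesenchymal genes lay above wild type in both ICD and EGFP neurons. A lower share of neurons, with the other cells in their old proportions, would raise glia markers alike. The pan-neuronal mean between ICD and wild type was -0.06, lower by fry only with the rat block (fry adjusted p = 0.0382) and not by camera. Over the 4 rats the fibroblast list exceeded the glia list by 1.25 ± 0.26 (SE, 95% interval 0.43 to 2.08). It exceeded the 5 glia markers of low wild-type level by 0.93 ± 0.13, and some of these lie near background. Those 5 moved unevenly, with Apoe at 1.72, Fabp7 at 0.73, Mbp at 0.39, Sox10 at 0.35 and Cdh19 at -0.31. The brighter glia markers, with wild-type means from 9.34 (Egr2) to 14.53 (Ngfr), changed by -0.55 (S100b) to 0.25 (Egr2). Whether markers at such levels could have risen more was not tested. The gap shows that the 2 lists did not rise evenly, but with such uneven and partly bright markers it does not exclude a lower share of neurons. One array standing apart is argued against, as the fibroblast mean was still 1.33 without the ICD array of rat 7. More RNA of fibroblast-like cells in the infected cultures remains a candidate explanation that these values do not decide. The 13 markers correlated at 0.67 on average within groups, and all 13 were detected on every wild-type array. That correlation does not point to a cell type, since it was 0.62 for cholesterol biosynthesis and 0.52 for the nerve injury list. That all 13 lay above wild type is the pattern itself and no support. A change of these genes within the cells already present, through infection or the overexpressed proteins, would give the same values and was not tested.

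Ptgds was higher in ICD than in EGFP neurons, though short of the threshold. One ICD array standing apart is not the whole of it, since the difference without the ICD array of rat 7 was 2.41. With the fibroblast list's mean as a covariate the difference was 2.42 (SE 1.08, 95% interval -0.08 to 4.92) against 3.08 without it, and with the rat as a block as well it was 2.47 (SE 1.46, 95% interval -1.28 to 6.21), so fibroblast-like RNA and an effect of the ICD on Ptgds cannot be told apart. In rats 2 and 3 the fibroblast means of ICD and EGFP differed by only -0.06 and 0.10 while Ptgds differed by 2.20 and 5.46, and in rat 6 they differed by 0.69 while Ptgds differed by -0.43. The 5.46 is that of rat 3, on whose EGFP array Ptgds was not detected. An effect of the ICD itself stays open.

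The count of 51 genes between ICD and wild type was reached by 1 of the 35 splits of the 8 arrays, the real one, and the highest other split gave 0. As arrays of one rat vary together, the real split is compared with the 8 splits that part all 4 rats. These are too few for a share under 5%; the real one gave 51 genes, or 198 with the rat block, and the highest other 0 with or without it. Gene counts of 0 are reached by every split (35 of 35 between ICD and EGFP, 35 of 35 between EGFP and wild type, 100 of 100 drawn regroupings for both controls together) and say nothing on chance. The highest other counts there were 199, 697 and 1. Those of 199 and 697 came from the split that sets rats 2 and 3 against rats 6 and 7, which points to a structure of the samples. For lists, 10 of 35 splits between ICD and EGFP gave at least 3 (highest other 7), 3 of 35 between ICD and wild type gave at least 7 (highest other 8), and 4 of 35 between EGFP and wild type gave at least 6 (highest other 8), so chance is not excluded for these counts. Of the 8 splits that part all 4 rats, 3, 2 and 1 reached these list counts, with 5, 8 and 4 as the highest other. There too 8 splits are too few for a share under 5%.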

How the results depend on the processing

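The alternatives with the background set as a block, either set of rats alone, the rat block with an array left out, and the title number as a block were added after the data had been seen. Counts between ICD and EGFP, EGFP and wild type, and ICD against both controls stayed at 0 under every alternative, except that the plain two-sample test at an unadjusted p under 0.05 gave 116, 420 and 37 genes, and that EGFP and wild type gave between 0 and 73 with the rat block and an array left out (73 without the ICD array of rat 7, 1 without the EGFP array of rat 7). The count of 51 between ICD and wild type was 8 without background correction, 8 with the authors' values, 8 with detection on all arrays, 0 without a filter on dim probes, where more probes share the adjustment, 98 with median scaling, 198 with the rat as a replicate block, 91 with the set as a block, 0 in rats 2 and 3 and 0 in rats 6 and 7, where fewer arrays are fitted, 252 with the title number as a block on the authors' values, 0 at an adjusted p under 0.01, and 806 unadjusted or 0 adjusted by the plain two-sample test. It ranged from 0 to 119 with each array left out, and from 0 to 276 with the rat block as well (0 without wild-type rat 7 or ICD rat 6, 1 without wild-type rat 3, 2 without ICD rat 3, 13 without wild-type rat 2). Apart from the alternatives that fit fewer or more values, the cause was not tested. All 51 genes remained with the rat block, median scaling and cyclic loess, and the 8 genes called without background correction, with the authors' values or under strict detection were among the 51. Median scaling moved the median of all probes between ICD and EGFP to 0.11. Where the rat block changed a call of a gene or list that the report names, its value stands there beside it. The block also moved counts over single lists between ICD and wild type, for cell cycle genes from 0 to 1 over the list alone and for heat shock proteins from 0 to 1 over all genes, and for proprioceptor markers between EGFP and wild type from 0 to 1 over the list alone.

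Of the list counts, the 3 between ICD and EGFP became 6 with the rat block, the set block or the title block, 0 in rats 2 and 3, 7 in rats 6 and 7, 0 with an estimated correlation and 0 by fry, and ranged from 3 to 8 with an array left out (2 to 7 with the rat block). The 7 between ICD and wild type became 3 under strict detection and 0 with an estimated correlation, and ranged from 6 to 8. The 6 between EGFP and wild type became 3 under strict detection, 3 in rats 6 and 7, 0 with an estimated correlation and 0 by fry, and ranged from 3 to 6 (3 without the EGFP array of rat 2). No list mean reversed; the fibroblast mean between ICD and wild type ranged from 1.14 to 1.85 over 41 alternatives. Of 97 pairs of a named gene and a comparison, the sign turned for those that follow. Nrg1 between ICD and EGFP was 0.0454 in rats 2 and 3 and ranged from -1.01 to 0.12 with an array left out. Nrg1 between EGFP and wild type was -0.25 with array weights, -0.40 in rats 2 and 3, and ranged from -0.57 to 0.42 with an array left out and from -0.17 to 0.23 with the rat block as well. In rats 2 and 3 the differences between ICD and EGFP were -0.10 for Col3a1, -0.11 for Col5a1, -0.083 for Ier2, -0.0136 for Klf4 and -0.0859 for Thbs2. Between EGFP and wild type Fos was -0.00491 in rats 2 and 3 and Zfp36 was -0.0692 in rats 6 and 7. Signals near background, as for Ptgds in wild type, limit the folds.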

Other observations

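Genes also differed between the rat numbers. With the group in the model, 999 of 8120 genes differed between the 4 rat numbers and 1684 between rats 2 and 3 and rats 6 and 7, with 743 higher and 941 lower in rats 2 and 3 (limma, adjusted p under 0.05). These samples were parted by array background and are not groups of the study. Each side holds 3 arrays from each of 2 rats, which were treated as 6 separate arrays although arrays of one rat vary together, so these counts, SEs and p-values make the difference look surer than 2 rats on each side allow. Higher in rats 2 and 3, with no overlap between 6 and 6 arrays, were the neuronal membrane glycoprotein gene Gpm6a by 1.73 ± 0.27, the mitochondrial ribosome gene Mrpl18 by 1.47 ± 0.09 and the Wnt potentiator gene Rspo2 by 1.22 ± 0.16 (log2 ± SE). Lower were the antioxidant enzyme gene Nqo1 by -1.45 ± 0.09, the transcription factor gene Etv4 by -1.55 ± 0.35 and Rgs2, a regulator of G protein signalling, by -1.40 ± 0.17. The genes were chosen after their values had been seen.

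By camera the nerve injury and regeneration list was higher in rats 2 and 3, with a mean of 0.57 and 8 of 19 genes past the threshold over all genes (adjusted p = 0.00092), and cholesterol biosynthesis was lower, with a mean of -0.54 and 5 of 11 genes past it (adjusted p = 0.0019). The p with an estimated correlation was 0.781 for both. By fry the nociceptor markers passed, with a mean of -0.34 (adjusted p = 0.0136, but 0.0724 by camera and 0.781 with an estimated correlation), and the other 2 lists did not (0.112 and 0.0884).

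The ICD array of rat 7 lay at -24.8 on the first principal component, which carried 38.0% of the variance, among the arrays of rats 2 and 3 (-25.8 to -3.90), while the other arrays of rats 6 and 7 lay at 18.8 to 28.2. Its median intensity of 156.1 was the highest of the 12 and lay outside the 92.7 to 109.5 of rats 2 and 3. Its deviations from the group mean did not follow the other 2 arrays of rat 7 (r of -0.05 and -0.06), so it is not settled whether its rat number is right. The values for each rat and with the rat block rest on that number. It also had the highest Ptgds value (12.03) and the lowest Nrg1 value (6.96).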
